A study of Mus musculus with 10 samples.

How the data were processed

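RNA was taken from fragments of at most 20 mg of each tumour and, per the labels' protocols, polyadenylated RNA with an integrity number above 7 was made into libraries with random-primed cDNA and NEBNext kits. The deposited table holds raw counts, whole numbers per gene and tumour, as the authors counted them, with no normalization. Per the submitters' processing notes, STAR and featureCounts were used with the mm10 build of the mouse genome, and their versions are not given in the sources used here. The annotation release, the strand setting and the treatment of reads that match several genes are not given either. Reads of overlapping or antisense genes, and of near-identical copies, can therefore not be told apart, and values of single members of such families are uncertain. The table has 55416 Ensembl gene IDs, of which 52083 (94%) matched a symbol in the reference tables used here, and 33312 had a count above 0. Of the IDs, 2147 belong to a number series that the GENCODE M21 annotation used here does not hold. Gene positions are those of GENCODE M21 on GRCm38, the build that mm10 names.

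Each column of the table was tied to its tumour by the tag at the end of the sample's title, and no column was left over. The vaccine group and the mouse number were taken from the titles. The cell line label of Arg2 vaccine mice 4, 5 and 6 reads Pan03, Pan04 and Pan05, while their titles say Pan02; these were analysed with their group, and a fit with only the tumours labelled Pan02 was run as an alternative. All 45 pairs of tumours differed by far more than counting noise (chi-square per degree of freedom of at least 11.7), so no library is a copy of another. Library totals ran from 17379184 to 34572540 counts. A count of 3 stood for at most 0.192 CPM.

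From these counts, the groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10), libraries were scaled with TMM, and the quasi-likelihood test was run with robust moderation and group as the only term. P-values were adjusted by Benjamini-Hochberg over the 16049 genes tested, with a threshold of 0.05. Fold changes are Arg2 vaccine against control vaccine. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values are scaled by the TMM library sizes, and log2 CPM used a prior count of 2. Intervals are at 95%; those of single counts are exact Poisson intervals.

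In all 34 gene lists of cell types, pathways and surrounding tissues were fixed before the data were examined, with 582 genes, of which 581 matched an ID. Lists with at least 5 tested genes, 33 in all, were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with the correlation estimated for each list. A list score is the mean over the list's genes of the z-score of log2 CPM across the 10 tumours. Where tumours were left out, the z-scores were taken anew across those kept. Score differences from fits with different tumours are therefore on unlike scales. Differences of scores were tested with exact two-sided permutation over all 210 splits of 10 tumours into 6 and 4.

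The genes named in the text followed a rule written before the data were examined. It took 14 genes of arginine metabolism and of immune cells whatever their p, the 5 higher and the 5 lower genes with the smallest p where none passed, and 2 genes with the smallest p from each list where none passed. Predicted genes were skipped in the second part, 1 among the higher and 3 among the lower genes. Some genes that the rule took are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

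On counts simulated from the mean level, the dispersion and the library sizes of these tumours, with the same mean in both groups except for 200 genes above 4 CPM, for 6 against 4 tumours and 15953 genes, the test recovered 40% of genes changed by 1 on the log2 scale, 84% of those changed by 2, 96% of those changed by 3 and 100% of those changed by 4, with 5 false calls. Each simulated gene was drawn independently of the others, so the shift of many genes together in Arg2 vaccine mice 3 and 5 was not simulated. These shares can therefore not be taken as the power of the test in the real tumours. The common biological coefficient of variation was 42.7% over the 10 real tumours and 25.9% without Arg2 vaccine mice 3 and 5.

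The alternatives were other scalings (RLE size factors, upper quartile, library totals alone), no filter and a stricter filter (at least 1 CPM in at least 4 tumours), leaving out each mouse in turn, the mouse number as a block, DESeq2 1.42.0, limma voom with and without sample quality weights, other settings of the quasi-likelihood test, a threshold of 0.1, a prior count of 0.5, fry, and exact permutation of list scores. Fits without Arg2 vaccine mice 3 and 5 were added after the data were seen. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.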

Results

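Bulk RNA sequencing was done on 10 whole subcutaneous tumours of Pan02 cells, a mouse pancreatic ductal adenocarcinoma line, grown in female C57BL/6 mice. The cells had been injected in the right flank. On days 11 and 17 the mice were given either a control vaccine, which was water emulsified in the oil adjuvant Montanide, or a peptide derived from Arg2 in the same adjuvant. Arg2 is the mitochondrial arginase, an enzyme that breaks arginine down to ornithine and urea. Tumours were collected on day 31, from 4 mice given the control vaccine and 6 given the Arg2 vaccine. Each tumour came from a different mouse, so the spread within a group is a spread between animals. Library totals ran from 17379184 to 34572540 counts. The highest total was that of Arg2 vaccine mouse 5, and the next highest was 22644524. A count of 3, the limit that a count of 0 allows, stood for 0.104 to 0.192 CPM (counts scaled by the normalized library size) in a library. Intervals and limits of this kind cover counting error only.

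The tumours of Arg2 vaccine mice 3 and 5 held almost no transcripts of 9 epithelial and pancreatic genes, taken here as markers of the carcinoma cells. Krt8, a keratin of simple epithelia, lay between 573 and 1510 CPM in the other 8 tumours and gave 2 counts in mouse 3 and 3 counts in mouse 5. The lowest of the other 8 tumours was 4480 times as high as mouse 3 (95% exact Poisson interval 1240 to 37000) and 5500 times as high as mouse 5 (1880 to 26700). Msln, the gene of the surface protein mesothelin, gave 0 counts in mouse 3, at least 1350-fold lower than the lowest of the other 8 with 3 counts as the floor in that library. Cldn2, a tight junction claudin, gave 0 counts in both, at least 616-fold lower in mouse 3 and at least 1130-fold lower in mouse 5. Pdx1, a transcription factor of the pancreas, also gave 0 counts in both. Summed over 9 such genes, the level was 0.0726% of the control mean in mouse 3 (0.0514 to 0.0997) and 0.0592% in mouse 5 (0.0448 to 0.0766). Krt19, another keratin of simple epithelia, made up 34 of the 38 summed counts of mouse 3 and 43 of the 57 of mouse 5, and was only 20.9 and 30.5 times lower there than in the lowest of the other 8. The sum was 49.2% in Arg2 vaccine mouse 1, 125% in mouse 2, 88.4% in mouse 4 and 106% in mouse 6. These 9 genes were chosen after their values were seen. No library of Pan02 cells alone was among the samples. The genes therefore cannot tell missing carcinoma cells from carcinoma cells that no longer express them. The first principal component of log2 CPM held 56% of the variance and placed these 2 tumours at 117.6 and 148.1, against -45.2 to -8.1 for the other 8. Most gene groups are therefore given for all 10 tumours and again without these 2, an alternative added after the data were seen.

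**Figure D1:**
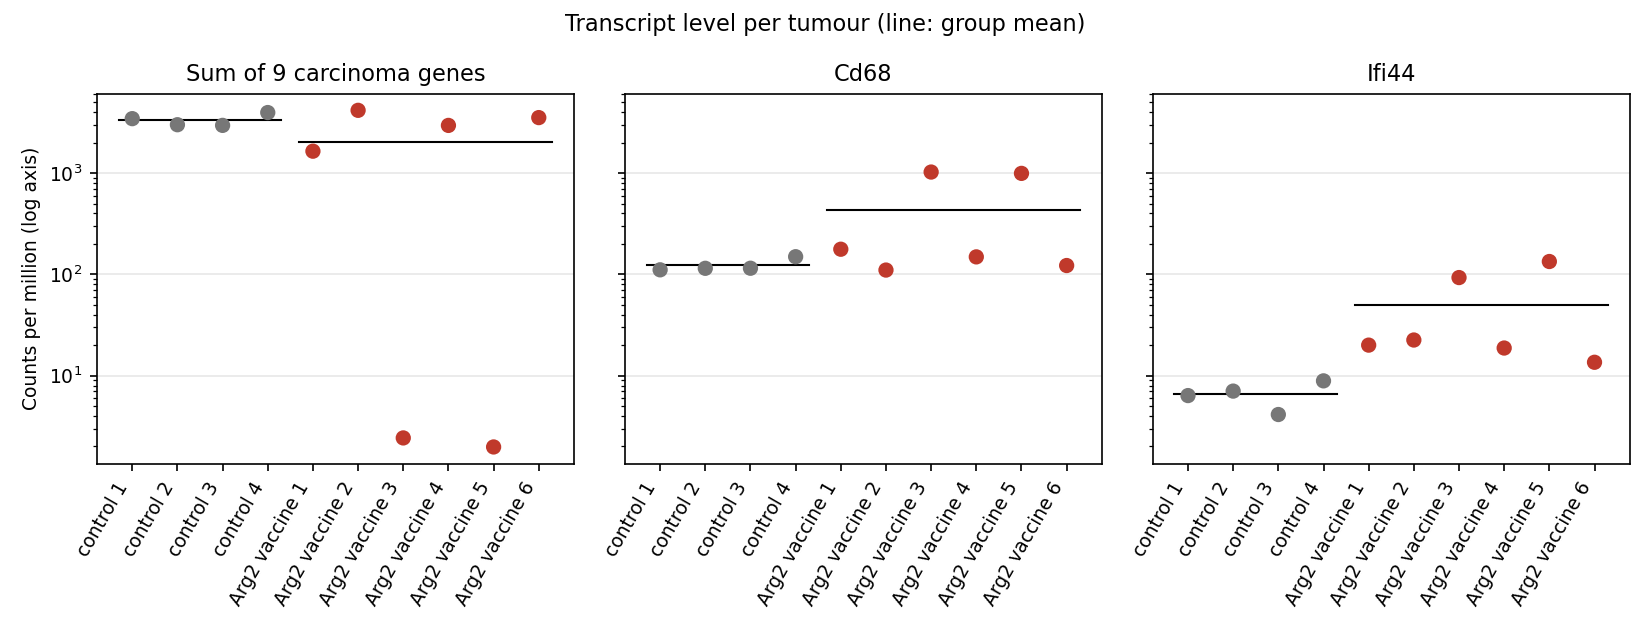
Level of the summed 9 carcinoma genes, of the macrophage gene Cd68 and of the interferon response gene Ifi44 in each tumour, in CPM on a log axis (grey, control vaccine; red, Arg2 vaccine; line, mean of the group). The carcinoma sum of Arg2 vaccine mice 3 and 5 was 2.43 and 1.979 CPM, and their Cd68 was 1025 and 994.3 CPM, while all 6 Arg2 vaccine tumours lay above the 4 control tumours for Ifi44.

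The first comparison asked which genes differed between Arg2 vaccine and control vaccine tumours. Of 16049 genes tested, 0 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, where the smallest adjusted p was 0.304. At an unadjusted p below 0.05 there were 2634 genes, 1822 higher and 812 lower in the Arg2 vaccine tumours. Other tools differed: DESeq2 called 295 genes, 267 higher and 28 lower, limma voom called 0, and limma voom with sample quality weights called 5, all of them higher. Those 5 were Lipe, Abcd2, Lrg1, Hp and Zbtb16, named here after their values were seen, and DESeq2 called all 5 as well. Of the 295 genes, 266 had been tested in edgeR, where all 266 had the same direction and an unadjusted p below 0.05. Without Arg2 vaccine mice 3 and 5, edgeR again called 0 genes, with 1807 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0514.

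Neither the 5 higher nor the 5 lower genes with the smallest p passed the adjusted threshold in edgeR (adjusted p = 0.304 for each gene of this paragraph). Abcd2, a peroxisomal fatty acid transporter (chromosome 15, 91145871 to 91191799, minus strand, GRCm38), was at 13.3 ± 1.28 CPM (SD, n = 6) against 5.89 ± 1.37 (n = 4), a log2 fold change of 1.17 (SE 0.17). Lipe, the hormone-sensitive lipase (chromosome 7, 25379527 to 25398710, minus strand), was at 29.3 ± 2.46 against 19.0 ± 1.62 CPM. Fabp4, a fatty acid binding protein of adipocytes and macrophages, was at 101.4 ± 41.6 against 17.8 ± 6.84 CPM (log2 fold change 2.51, SE 0.40). Vit, a matrix protein gene, differed by 2.46 on the log2 scale (SE 0.40), at 1.56 CPM against 0.277 CPM. Tnfsf10, the death ligand TRAIL, was at 23.3 ± 7.58 against 8.08 ± 2.11 CPM. Among lower genes, Inhba, the activin A subunit (chromosome 13, 16011851 to 16031621, plus strand), was at 65.2 ± 10.6 against 115 ± 34.4 CPM (log2 fold change -0.82, SE 0.20). Espl1, the protease separase that parts sister chromatids, had a log2 fold change of -0.39 (SE 0.09) and Incenp, a chromosomal passenger protein, -0.60 (SE 0.15). Utp4, a ribosome biogenesis gene, had -0.59 (SE 0.14) and Micall2, an actin and junction trafficking gene, -0.59 (SE 0.15). For each of these 10 genes all 6 Arg2 vaccine tumours lay outside the range of the 4 control tumours, and the exact two-sided permutation p of log2 CPM was 0.00476, the smallest that 210 splits can give before any adjustment; genes picked for the smallest p of 16049 separate in this way by that choice. With mice 3 and 5 left out, the log2 fold change of Abcd2 was 1.18, of Lipe 0.61, of Fabp4 2.12 and of Inhba -0.70.

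Arg2 itself, the source of the vaccine peptide (chromosome 12, 79130777 to 79156301, plus strand, protein-coding), was a low transcript in these tumours and did not differ beyond the spread between mice. It was at 3.46 ± 2.95 CPM (SD, n = 6) in Arg2 vaccine and 2.73 ± 1.66 CPM (n = 4) in control vaccine tumours. The log2 fold change was 0.34 (SE 0.66; 95% interval -1.13 to 1.82; edgeR adjusted p = 0.765), and the exact two-sided permutation p was 0.848. Its 2 highest tumours were those of mice 5 and 3, at 8.72 and 4.99 CPM, and without both the log2 fold change was -0.64. Arg1, the cytosolic arginase of alternatively activated macrophages (chromosome 10, 24915221 to 24927484, minus strand), was at 118 ± 76.6 against 115 ± 126 CPM, a log2 fold change of 0.04 (SE 0.70). This rested on control mouse 4, at 303 CPM against 38.7 to 70.9 CPM in the other controls. Without that mouse the Arg1 log2 fold change was 1.17 (edgeR adjusted p = 0.375). The list of 26 measured arginine and polyamine genes was not called (camera adjusted p = 0.875): 14 were higher and 12 lower. Its median and mean log2 fold changes, 0.03 and 0.19, were above 0 while the test's direction was down. Within it Prmt1, a protein arginine methyltransferase, had -0.44 (SE 0.20) and Ddah2, which breaks down methylarginines, 0.70 (SE 0.32).

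Interferon response and antigen presentation genes were higher in the Arg2 vaccine tumours as groups, but no group passed once the correlation between its genes was estimated. All 25 measured genes of the type I interferon response list were higher, with a median log2 fold change of 2.36 (camera adjusted p = 1.68e-11; adjusted p = 0.584 with an estimated correlation). Adjusted over the list alone 24 of the 25 passed, and 0 passed over all genes tested. Ifi44 was at 50.4 ± 50.8 CPM (SD, n = 6) against 6.61 ± 1.97 (n = 4), and Ifi27l2a at 176.4 ± 192 against 17.2 ± 4.24 CPM; for both genes all 6 Arg2 vaccine tumours lay above every control tumour. Mice 3 and 5 set much of this size, with Ifi27l2a at 419.5 and 427.4 CPM against 38.2 to 81.5 CPM in the other 4. Without them the list's median was 0.90 (camera adjusted p = 1.17e-24; adjusted p = 0.277 with an estimated correlation). All 24 genes of the interferon gamma response list were higher as well (median 0.77, camera adjusted p = 3.76e-09; adjusted p = 0.567 with an estimated correlation), and 0 passed when adjusted over the list alone. Gbp7, an interferon-induced GTPase, was at 142 ± 31.5 against 82.1 ± 18.6 CPM, and Gbp8 had a log2 fold change of 1.08 (SE 0.32). All 12 MHC class II presentation genes were higher (median 0.73, camera adjusted p = 9.99e-07; adjusted p = 0.567 with an estimated correlation), and 7 passed when adjusted over the list alone. H2-Ab1, a class II chain, was at 1689 ± 524.6 against 861.3 ± 295.4 CPM, and H2-Eb1 at 1508 ± 380.6 against 819.1 ± 308.8 CPM. All 20 MHC class I presentation genes were higher (median 0.81, camera adjusted p = 4.31e-06; adjusted p = 0.584 with an estimated correlation), 0 of them passing over the list alone; among them the immunoproteasome subunits Psmb9 and Psmb8 had log2 fold changes of 1.23 (SE 0.43) and 1.05 (SE 0.38). Without mice 3 and 5 the medians were 0.54, 0.61 and 0.27 for the interferon gamma, class II and class I lists. Several members of these families have near-identical copies, so the values of single Gbp, H2 and Ifi genes are uncertain where reads were shared.

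**Figure D2:**
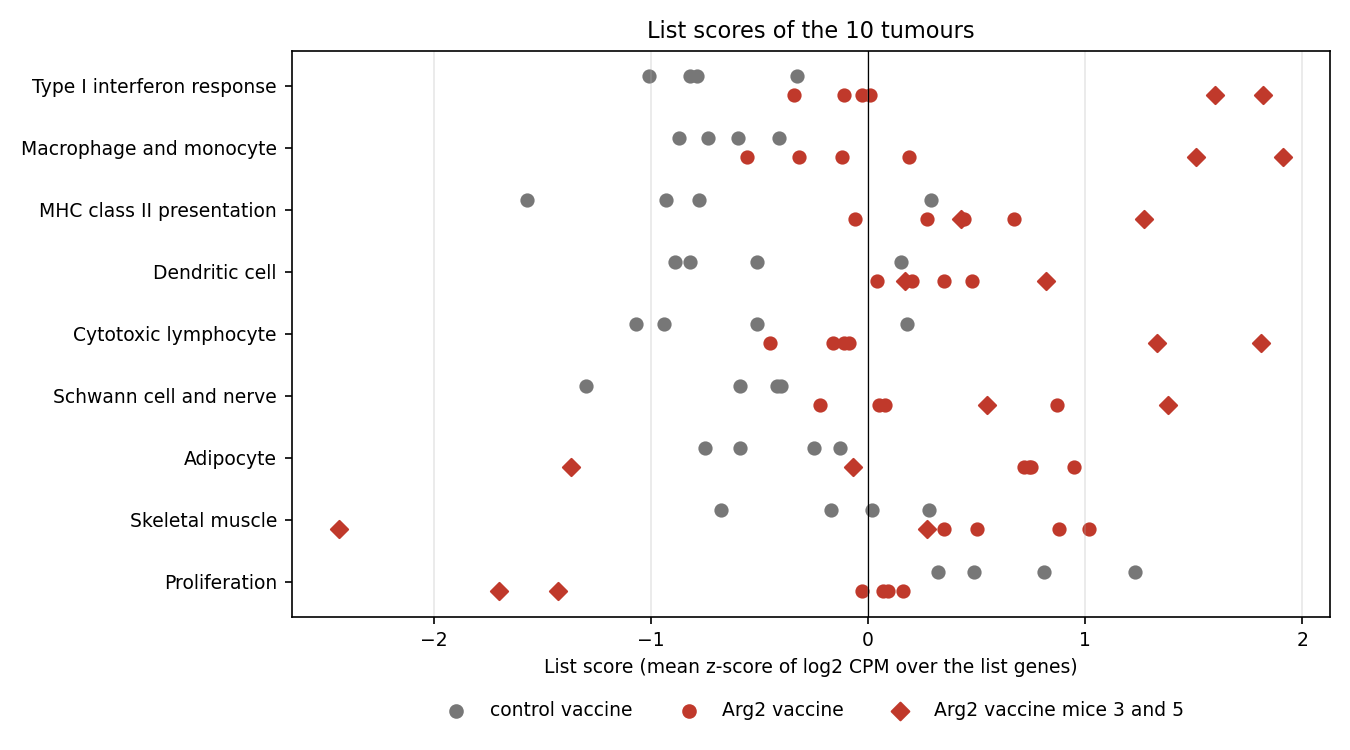
Scores of 9 gene lists in each of the 10 tumours, as the mean z-score of log2 CPM over the list's genes (grey, 4 control vaccine tumours; red, 6 Arg2 vaccine tumours; diamonds, Arg2 vaccine mice 3 and 5). For type I interferon the diamonds lie at 1.6 and 1.82 and the other Arg2 vaccine tumours between -0.34 and 0.01, against -1.01 to -0.33 in the controls; for proliferation all 6 Arg2 vaccine tumours lie below the controls.

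Macrophage and monocyte, dendritic cell and chemokine genes were higher as lists, and for macrophages and monocytes mice 3 and 5 lay far above the rest, with scores of 1.51 and 1.91 against at most 0.19. All 18 macrophage and monocyte genes were higher (median 1.29, camera adjusted p = 4.55e-07; adjusted p = 0.584 with an estimated correlation), and 16 passed when adjusted over the list alone. Cd68, a macrophage lysosomal protein, was at 1025 CPM in mouse 3 and 994.3 CPM in mouse 5, while the other 4 Arg2 vaccine tumours lay between 110.4 and 177.3 CPM and the controls between 111 and 149.6 CPM. Ccr2, the receptor that draws monocytes into tissue, was at 155 ± 76.5 against 64.5 ± 15.5 CPM, and Ly6c2, a monocyte surface antigen, had a log2 fold change of 4.39 (SE 1.47). Ly6c2 was at 140.5 and 244.5 CPM in mice 3 and 5 and at no more than 21.2 CPM elsewhere. With mice 3 and 5 left out, the macrophage median was 0.44 and the Ly6c2 log2 fold change 1.38. The Cd68 log2 fold change was then 0.17, so that the Cd68 difference rested on them. Of 14 genes of classical macrophage activation 10 were higher (median 0.96, camera adjusted p = 0.0432; adjusted p = 0.645 with an estimated correlation; 0 over the list alone), and the call was lost without mice 3 and 5, where the median was 0.11 and the adjusted p 0.405. Nos2, the inducible nitric oxide synthase, was at 59.0 ± 69.2 against 14.9 ± 21.3 CPM, with 168.5 and 124.1 CPM in mice 3 and 5. Control mouse 4 was at 46.8 CPM and the other controls at 2.99 to 5.59 CPM. The Nos2 log2 fold change was 1.99, and 3.80 without control mouse 4. Without Arg2 vaccine mice 3 and 5 it was 0.04. Irf5 and the costimulatory receptor gene Cd40 had log2 fold changes of 1.52 (SE 0.58) and 1.64 (SE 0.63). Of 18 genes of alternative activation 14 were higher (median 0.82, camera adjusted p = 0.0115; adjusted p = 0.584 with an estimated correlation), 3 of them passing over the list alone. Clec10a, a lectin of tissue macrophages and dendritic cells, was at 76.5 ± 38.9 against 26.6 ± 12 CPM and above every control in 6 of 6 tumours. Lyve1 was at 23.1 ± 13.9 against 4.32 ± 2.60 CPM, and Mrc1, the mannose receptor, had 0.65 (SE 0.30). Of 16 dendritic cell genes 14 were higher (median 0.64, camera adjusted p = 0.000549; adjusted p = 0.567 with an estimated correlation; 0 over the list alone); Batf3, a transcription factor of cross-presenting dendritic cells, had 1.36 (SE 0.43) and Snx22 0.67 (SE 0.20). Of 27 chemokine genes 22 were higher (median 1.59, camera adjusted p = 0.000472; adjusted p = 0.584 with an estimated correlation; 0 over the list alone), with Cxcl12 at 258 ± 222 against 46.3 ± 28 CPM and Ccl9 at 414 ± 386 against 81.4 ± 44.9 CPM. Over the other 8 tumours the median was 0.32 for chemokines, 0.41 for alternative activation and 0.32 for dendritic cells, and all 3 lists were still called by camera (adjusted p = 0.747, 0.557 and 0.405 with an estimated correlation). The alternative activation call was lost without control mouse 1 (camera adjusted p = 0.0795) or Arg2 vaccine mouse 4 (0.0508).

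Neutrophil genes were not called (10 of 13 higher, median 0.62, camera adjusted p = 0.41), and without mice 3 and 5 their median was -0.73. Clec4e and Clec4d, myeloid lectins of that list, were at 218.5 and 210.3 CPM in mouse 3 and 243.3 and 222.7 CPM in mouse 5, and at no more than 39.3 CPM in any of the other 8 tumours. Mast cell and eosinophil genes were lower in 9 of 11 (median -1.08, camera adjusted p = 0.0166; adjusted p = 0.615 with an estimated correlation; 0 over the list alone). Cma1, a mast cell chymase, had -1.29 (SE 0.51), with control mouse 3 at 421.5 CPM and every other tumour at no more than 123.1 CPM. The call was lost without control mouse 3, where the median was -0.47, without Arg2 vaccine mouse 2, and without mice 3 and 5 of the vaccine group, where the median was -0.72 (camera adjusted p = 0.0676). Ccr3, an eosinophil chemokine receptor of the same list, went the other way at 1.73 (SE 0.60).

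T cell, cytotoxic, NK and B cell genes were higher as lists, with wide spreads between mice, and regulatory T cell genes were not called. All 19 T cell genes were higher (median 0.81, camera adjusted p = 1.52e-05; adjusted p = 0.584 with an estimated correlation), and so were all 16 cytotoxic lymphocyte genes (median 1.35, camera adjusted p = 4.57e-05; adjusted p = 0.584 with an estimated correlation); 0 genes of either passed over the list alone. Cd8a was at 19.5 ± 11.4 CPM (SD, n = 6) against 8.96 ± 4.60 (n = 4), a log2 fold change of 1.13 (SE 0.48), and Cd8b1 had 1.30 (SE 0.52). Cd3e had 0.87 (SE 0.42), Skap1 1.07 (SE 0.43) and Cd4 0.62 (SE 0.37). Ifng, the gene of interferon gamma, was at 2.94 ± 2.25 against 0.915 ± 0.365 CPM, and the granzyme gene Gzma at 8.85 ± 10.7 against 0.935 ± 0.664 CPM. Gzmb had 1.36 (SE 0.95) and Prf1, the gene of perforin, 0.78 (SE 0.60). Over the other 8 tumours the medians were 0.25 for T cells and 0.36 for cytotoxic lymphocytes, and Gzmb was at -0.31. The NK cell list (9 of 10 higher, median 1.78, camera adjusted p = 0.0357; adjusted p = 0.631 with an estimated correlation; 0 over the list alone) had a median of 0.02 and an adjusted p of 0.739 without them. Its receptor genes Klre1 and Klrc2 had 1.83 (SE 0.69) and 2.32 (SE 0.92). The T cell checkpoint list was higher in 12 of 13 (median 0.55, camera adjusted p = 0.0156; adjusted p = 0.631 with an estimated correlation; 0 over the list alone) and lost its call without mice 3 and 5, at 0.16 and an adjusted p of 0.105. Cd274, the gene of PD-L1, was at 114.7 ± 95.4 against 40.8 ± 15.6 CPM, Vsir had 0.94 (SE 0.33) and Pdcd1, the gene of PD-1, 0.55 (SE 0.41). Foxp3, the transcription factor of regulatory T cells, was at 13.3 ± 4.36 against 14.6 ± 7.55 CPM, and the regulatory T cell list was not called (8 of 12 higher, median 0.10, camera adjusted p = 0.41). This rested on control mouse 4, whose score was 1.34 against at most -0.52 in the other controls. Without it the list was called higher (median 0.47, camera adjusted p = 0.00232) and Foxp3 was at 0.28. That call used the preset correlation, and an estimated correlation was not tried without that mouse. Of the regulatory T cell genes Il10 had 2.02 (SE 0.88) and Ikzf2 0.37 (SE 0.23). All 7 B cell genes were higher (median 0.80, camera adjusted p = 0.0143; adjusted p = 0.584 with an estimated correlation), and 11 of 13 plasma cell and immunoglobulin genes (median 0.59, camera adjusted p = 0.0143; adjusted p = 0.633 with an estimated correlation), with 0 passing over either list alone. Cd22 had 1.49 (SE 0.67), Bank1 0.80 (SE 0.38), Iglc3 1.93 (SE 0.73) and Ighg1 1.83 (SE 1.09). Without mice 3 and 5 neither list was called, at camera adjusted p = 0.0868 and 0.14. The plasma cell median ran from 0.25 to 2.26 as each mouse was left out, and its call was lost without any 1 of 5 mice.

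**Figure D3:**
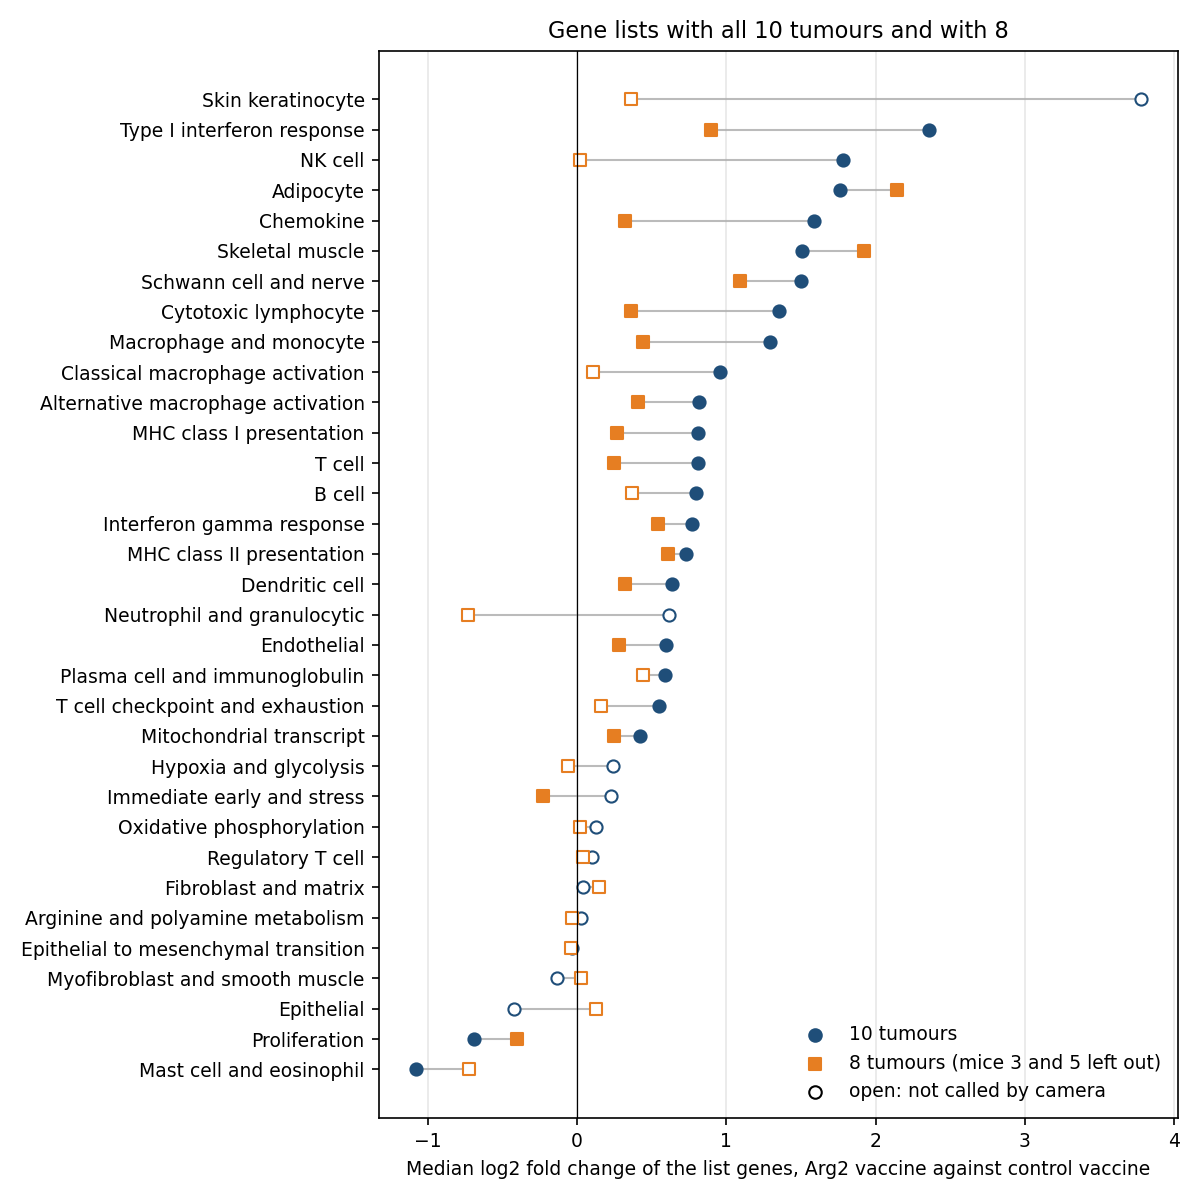
Median log2 fold change of each gene list, Arg2 vaccine against control vaccine, with all 10 tumours (blue circles) and with the 8 that leave out Arg2 vaccine mice 3 and 5 (orange squares); filled symbols were called by camera with its preset correlation. The type I interferon median went from 2.36 to 0.90 and the NK cell median from 1.78 to 0.02, while the adipocyte median went from 1.76 to 2.14.

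Proliferation genes were lower in the Arg2 vaccine tumours. Of 27 measured, 26 were lower (median -0.69, camera adjusted p = 2.2e-14; adjusted p = 0.567 with an estimated correlation), and 0 passed when adjusted over the list alone. Bub1b, a spindle checkpoint kinase, was at 32.2 ± 5.95 CPM (SD, n = 6) against 46.9 ± 6.00 (n = 4), and Cenpa, the centromere histone, at 33.1 ± 5.58 against 45.0 ± 2.24 CPM; both were below every control in 6 of 6 tumours. The list score was lower in 6 of 6 as well, at -1.43 and -1.7 in mice 3 and 5 and between -0.03 and 0.16 in the other 4, against 0.32 to 1.23 in the controls (exact two-sided permutation p = 0.0381; adjusted 0.21). Markers used for cell composition moved along with it. Mice 3 and 5 held almost no transcripts of the 9 carcinoma marker genes. Mice 1, 2, 4 and 6 had higher fat and muscle scores than every control. Without mice 3 and 5 the median was -0.40 (camera adjusted p = 1.51e-19; adjusted p = 0.391 with an estimated correlation).

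Nerve, fat, muscle and vessel genes were higher as lists, while skin keratinocyte genes were not called. All 11 Schwann cell and nerve genes were higher (median 1.5, camera adjusted p = 3.39e-06; adjusted p = 0.567 with an estimated correlation), and 7 passed when adjusted over the list alone. Scn7a, a sodium channel gene, was at 27.7 ± 13.2 CPM (SD, n = 6) against 6.16 ± 3.25 (n = 4) and above every control in 6 of 6 tumours. Of 14 adipocyte genes 11 were higher (median 1.76, camera adjusted p = 0.000156; adjusted p = 0.584 with an estimated correlation), 3 of them passing over the list alone. The adipocyte score was lowest of all 10 tumours in mouse 5, at -1.37. Without mice 3 and 5 the median was 2.14, and this was the only list of 33 that passed there with an estimated correlation (adjusted p = 0.021). By exact permutation of the scores over those 8 tumours it did not pass (adjusted p = 0.236), and neither did any other list. All 18 skeletal muscle genes were higher (median 1.51, camera adjusted p = 0.0411; adjusted p = 0.727 with an estimated correlation; 0 over the list alone), with Pygm, the muscle glycogen phosphorylase, at 1.80 (SE 0.97) and Pvalb, a calcium buffer of fast fibres, at 2.42 (SE 1.23). The muscle score of Arg2 vaccine mouse 5, -2.44, was the lowest of all 10 tumours. Between the groups the muscle score differed by 0.24 (exact two-sided permutation p = 0.819). The muscle call was lost without control mouse 2 (camera adjusted p = 0.0902), control mouse 3 (0.227) or Arg2 vaccine mouse 1 (0.256), 2 (0.265), 4 (0.0877) or 6 (0.115). Of 18 endothelial genes 17 were higher (median 0.60, camera adjusted p = 0.000262; adjusted p = 0.608 with an estimated correlation; 0 over the list alone), with the angiopoietin receptor gene Tek at 22.8 ± 15.1 against 6.50 ± 1.24 CPM and Eng at 0.67 (SE 0.25). The endothelial scores were 1.14, 1.14 and 1.28 in mice 1, 3 and 5 and -0.86, -0.66 and -0.05 in mice 2, 4 and 6, against -0.73 to -0.04 in the controls. Over the 8 tumours without mice 3 and 5 the median was 0.28 for endothelial, 1.09 for nerve and 1.92 for muscle genes, and all 3 lists were still called by camera (adjusted p = 0.747, 0.391 and 0.277 with an estimated correlation). Apart from these tissues, all 8 measured mitochondrial transcripts were higher (median 0.42, camera adjusted p = 0.0169, adjusted p = 0.631 with an estimated correlation, 0 over the list alone). Of these mt-Nd2 was at 0.48 (SE 0.23) and mt-Nd4 at 0.41 (SE 0.21). The mitochondrial call was lost without control mouse 3 (camera adjusted p = 0.0601) or Arg2 vaccine mouse 2 (0.0832).

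The remaining lists were not called over all 10 tumours. Fibroblast and matrix genes split evenly (12 of 22 higher, median 0.04, camera adjusted p = 0.617), with Pdgfra at 0.56 (SE 0.22) and Fn1, the gene of fibronectin, at -0.41 (SE 0.20). Myofibroblast and smooth muscle genes had a median of -0.13 (6 of 14 higher, camera adjusted p = 0.226), with Actg2 at -1.41 (SE 0.48) and Myh11 at 0.83 (SE 0.35). Epithelial genes were lower in 9 of 12 (median -0.42, mean 0.09, direction down, camera adjusted p = 0.0576), and over the 8 tumours without mice 3 and 5 the median was 0.13. Of that list Epcam, a surface adhesion molecule, reached 33.8 CPM in mouse 3, whose Krt8 was near 0. Genes of epithelial to mesenchymal transition had a median of -0.03 (9 of 16 lower, camera adjusted p = 0.563), and 1 of them, Inhba, passed when adjusted over the list alone; Tgfbi had 0.83 (SE 0.45). Hypoxia and glycolysis genes were higher in 16 of 23 (median 0.24, camera adjusted p = 0.0776), with Adm, the gene of adrenomedullin, at 1.29 (SE 0.33) and Pfkfb3 at 1.04 (SE 0.38). Oxidative phosphorylation genes were higher in 17 of 25 (median 0.13, camera adjusted p = 0.187), with Ndufb3 at 0.53 (SE 0.20) and Uqcrq at 0.42 (SE 0.16). Skin keratinocyte genes had a median of 3.78 (13 of 14 higher, camera adjusted p = 0.801), which came from mouse 3, where Krt10 was at 3231 CPM; without mouse 3 the median was 0.04, and 4 of 6 Arg2 vaccine scores lay below every control. Immediate early genes had a median of 0.23, a mean of -0.12 and a test direction of down (camera adjusted p = 0.757). Over the 8 tumours without mice 3 and 5 this list was called lower, with a median of -0.23 (camera adjusted p = 0.0241; adjusted p = 0.747 with an estimated correlation). Fosb was at 385.2 CPM in control mouse 4 and at no more than 12.03 CPM elsewhere, and Egr1 had -1.24 (SE 0.33). The erythrocyte list had fewer than 5 tested genes and was not tested; Alas2 had 2.27 (SE 0.87) and Hbb-bt 2.66 (SE 1.09), both under 5 CPM in every tumour.

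Scored per tumour and tested with the mouse as the replicate, 0 of 33 lists passed an exact two-sided permutation test over 210 splits after adjustment. The smallest p was 0.00952, for dendritic cells (score difference 0.86), followed by 0.0143 for MHC class II presentation (1.25) and for Schwann cells and nerve (1.13), each with an adjusted p of 0.157. The type I interferon score differed by 1.23 (exact permutation p = 0.0524, adjusted 0.247) and the macrophage score by 1.09 (exact permutation p = 0.0667, adjusted 0.275).

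The balance between effector and regulatory lymphocyte transcripts was compared as the cytotoxic lymphocyte score minus the regulatory T cell score. It was 0.26 ± 0.95 (SD, n = 6) in Arg2 vaccine and -0.38 ± 0.53 (n = 4) in control vaccine tumours, a difference of 0.64 (exact two-sided permutation p = 0.271). The classical minus the alternative macrophage activation score was 0.02 ± 0.72 against -0.02 ± 0.27, a difference of 0.04 (exact two-sided permutation p = 0.943). Over the other 8 tumours they were 0.35 (exact permutation p = 0.343) and -0.28 (p = 0.371).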

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

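Of 246 groups of values tested (123 values in each of the 2 vaccine groups), 16 had 1 tumour far from the rest of its group, judged by its gap to the nearest other tumour divided by the range; chance flags about 1 in 20 groups, here 12.3. The tests of explanations in this part, and the sums behind them, were all chosen after the values were seen.

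Control mouse 4 stood above the other 3 controls in 9 of them. Its T cell score was 0.63 against at most -0.86, its regulatory T cell score 1.34 against at most -0.52, its T cell checkpoint score 0.64 against at most -0.67 and its immediate early score 1.2 against at most -0.29. Its log2 CPM was 7.23 for Cd68 against at most 6.85, 6.11 for Irf5 against at most 5.37, 12.5 for Fn1 against at most 12.05 and 8.59 for Fosb against at most 3.14. Alas2, an enzyme of haem synthesis in red cell precursors, was at -0.5 log2 CPM in control mouse 4 against at most -1.68. Micall2 was at 4.25 log2 CPM in control mouse 2 against at least 4.41. In the Arg2 vaccine group, Ccr3 was at 0.58 log2 CPM in mouse 2 against at least 2.22 in the other 5.

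Arg2 vaccine mouse 5 had the deepest library, 34572540 counts (34.57 with the last 6 digits as decimals) against at most 21956215 in its group. Its skeletal muscle score was -2.44 against at least 0.27, with Pvalb at -3.39 log2 CPM against at least 5.28 and Pygm at 0.76 against at least 5.98. Its Micall2 was at 3.23 log2 CPM against at least 3.71.

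The tumours of Arg2 vaccine mice 3 and 5 held almost no transcripts of the 9 carcinoma marker genes. For mouse 5, skin, muscle or fat sampled in place of tumour is argued against. Its summed fat genes were at 67.7% of the control mean (66.3 to 69.1), the skin genes at 30.9% and the muscle genes at 2.08%. Of its 8675 summed fat counts 4352 were of Fabp4, a gene of macrophages as well. Tissues other than skin, muscle and fat were not tested for either tumour, so another tissue in place of tumour stays open. For mouse 3 skin may be part of the sample, since summed skin keratinocyte genes were at 6700% of the control mean, or 10610 CPM. No skin library gives the share that this stands for. Mouse 6 had 368% of the control mean for skin and 106% for the carcinoma genes. Raised skin genes alone therefore do not show that tumour tissue was missing. Another cell line shared by the labels Pan03 to Pan05 is argued against as the cause in both tumours. Mouse 3 is labelled Pan02, and the tumour labelled Pan03 had 88.4% of the control mean of the 9 carcinoma genes. Mouse 5 is the only tumour labelled Pan04, so another line in that tumour alone stays open. Loss of the carcinoma cells after the Arg2 vaccine stays open. Of all pairs of the 10 tumours a share of 0.333 lies within the vaccine group. The 2 tumours can therefore not be told apart from chance. Carcinoma cells that no longer express the 9 genes would give the same values, and this was not tested.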

How the results depend on the processing

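Among 33 lists, camera's direction and call were the same with RLE size factors, upper quartile scaling and library totals alone. The called gene count of 0 held in every edgeR setting, in limma voom and without each mouse in turn. It did not hold with DESeq2 (295 genes, 267 higher and 28 lower) or with voom quality weights (5, all 5 higher). The 20 higher and 2 lower lists became 0 and 0 with an estimated correlation, with fry and with exact permutation of the scores, and 1 and 0 for 8 tumours with an estimated correlation; leaving out each mouse gave 15 to 22 higher and 2 to 3 lower lists. The mouse number as a replicate block gave 0 genes, 19 higher and 3 lower lists. No control mouse had the number 5 or 6, so Arg2 vaccine mice 5 and 6 added nothing to the group difference in that fit. Same-numbered tumours deviated together with correlations of 0.127, 0.109, -0.04 and 0.033, and no control tumour correlated best with its own number, so the number was not taken as a pairing. Under that block Krt10 was at -0.39, the fibroblast list at 0.03 with direction down and the keratinocyte list at -1.03.

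For 8 tumours without Arg2 vaccine mice 3 and 5 (chosen after the data were seen) these changed direction: Arg2 -0.64 (difference in mean log2 CPM -0.51), Arg1 -0.44, Gzmb -0.31, Clec4d -0.084, Krt19 0.32, Wfdc2 0.10, Gpnmb -0.021 and the classical minus alternative score -0.28. List medians there were -0.73 for neutrophils, 0.03 for myofibroblasts, -0.06 for hypoxia and 0.36 for keratinocytes (direction down), the same with an estimated correlation. With only tumours labelled Pan02, Arg2 was at -0.01 (-0.015), Arg1 at -0.03 (-0.025), and the regulatory T cell, arginine and fibroblast lists at -0.20, 0.03 (direction up) and -0.05. Arg1 was at -0.10 (-0.095) with library totals alone, -0.02 (-0.022) with no filter and -0.002 in DESeq2. With quality weights Foxp3 was at 0.43, Krt19 at 0.12 and Gpnmb at -0.22. The keratinocyte list was at 3.56 with direction down with no filter, and fry turned the arginine list (0.03) to up.

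Leaving out each mouse gave ranges of -0.30 to 1.17 for Arg1, -0.19 to 0.71 for Arg2 (-0.2 to 0.46 as a difference in mean log2 CPM), -0.33 to 0.28 for Foxp3, -0.67 to 0.24 (0.245) for Krt19 and -0.15 to 0.18 for the classical minus alternative score. List medians ranged from -0.07 to 1.2 for neutrophils, 0 to 0.07 for arginine, -0.12 to 0.23 for fibroblasts, 0.04 to 5.19 for keratinocytes and 0.04 to 0.58 for immediate early genes. Calls of 8 lists were lost without at least 1 mouse: NK cell, T cell checkpoint, plasma cell, classical and alternative macrophage activation, mast cell, skeletal muscle and mitochondrial. Leaving out 1 mouse also gave calls: regulatory T cell higher (0.47, camera adjusted p = 0.00232) and hypoxia higher (0.45, 0.000409) without control mouse 4, neutrophil higher (1.2, 0.0195) without control mouse 3, hypoxia higher (0.29, 0.00952) and myofibroblast lower (-0.28, 0.0246) without Arg2 vaccine mouse 1, and epithelial lower without control mouse 3 or Arg2 vaccine mouse 2, 4 or 6 (-0.69 to -0.56, adjusted p from 0.0124 to 0.0464). The cytotoxic minus regulatory score kept its direction, from 0.24 to 0.84. List calls without 1 mouse used the preset correlation alone. The cause of these changes was not tested.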

Other observations

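The tests in this part, the splits of the tumours included, were all chosen after the values were seen. Gpnmb and Lpl, genes outside the lists, separated the same 2 tumours. Gpnmb, a glycoprotein of lipid-laden macrophages, was at 2298 CPM in Arg2 vaccine mouse 3 and 2383 CPM in mouse 5, and at no more than 138.2 CPM in the other 8 tumours. Lpl, the lipoprotein lipase, was at 2306 and 1984 CPM in these and at 88.4 to 198.8 CPM in the other 4 Arg2 vaccine tumours, against 29.9 to 58.2 CPM in the controls. Plin1 and Cfd, genes of the adipocyte list, went the other way in mouse 5, at 0.278 and 2.54 CPM. They were at 3.71 to 14.9 CPM and 21.9 to 81.5 CPM in the other Arg2 vaccine tumours. The controls lay at 0.985 to 3.33 CPM and 8.47 to 23.2 CPM, so mouse 3, at 3.71 and 21.9 CPM, was close to them. These genes were chosen after their values were seen.

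The interferon and macrophage lists were called higher by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.584 for both) nor by exact permutation of their scores (adjusted 0.247 and 0.275), and the macrophage score of Arg2 vaccine mouse 2, -0.56, lay within the control range. Whether mice 3 and 5 alone set this cannot be told apart from a shift in all 6: over the other 8 tumours the type I interferon score differed by 1.36 with an exact permutation p of 0.0571, and 5 of 6 Arg2 vaccine tumours lay above every control. A lower share of carcinoma cells may also raise every other cell type. The macrophage mean log2 CPM minus that of fibroblast and matrix genes was higher by 0.99 in the Arg2 vaccine tumours (exact permutation p = 0.195). Against endothelial, dendritic cell and T cell genes it was higher by 0.59, 0.58 and 0.31 (exact permutation p = 0.133, 0.31 and 0.352). Each of these 4 comparisons had an adjusted p of 0.352, so a lower share of carcinoma cells stays open too. The Arg2 vaccine itself stays among the open explanations.

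Adipocyte and skeletal muscle transcripts were higher in Arg2 vaccine mice 1, 2, 4 and 6. Adjacent tissue in the sampled fragment stays open as an explanation: without mice 3 and 5, 29 of the 32 tested genes of both lists had a log2 fold change above 0.5, but the pattern was found in these genes, so this decides nothing. A rise set by the Arg2 vaccine is left open. The mean of both lists differed by 0.76 over 10 tumours (exact permutation p = 0.619). Over 8 it differed by 1.91 (exact permutation p = 0.0286, the smallest that 70 splits allow for a two-sided test). The 8 leave out mouse 5, whose fat and muscle scores, -1.37 and -2.44, were the lowest of all 10 tumours. The pattern was seen in the Arg2 vaccine tumours that were kept, so the p over 8 decides nothing either.

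Other splits of the tumours gave as many genes at an unadjusted p below 0.05 and as many called lists, so chance cannot be excluded for these counts. No split can give fewer than the real 0 genes past the adjusted threshold, so all 100 splits of the 10 tumours (the highest of the others 27) and all 35 of the 8 tumours (the highest of the others 0) decide nothing there. Of the 100 splits into 6 and 4, the real one included, 13 gave at least the real 2634 genes at an unadjusted p below 0.05, the highest of the others being 4655, and 23 gave at least the real 22 called lists, the highest of the others being 28. Among these 100, mice 3 and 5 were together in the group of 4 in 16 splits, of which 2 called genes (27 and 20) and 14 called 0. These 16 hold all 12 other splits run with at least 2634 genes. In the 35 of the 100 with both in the group of 6, as in the real one, the next highest was 2284. This points to a structure of the samples that those 2 tumours make. Of the 35 splits of the 8 tumours into 4 and 4, 2 gave at least the real 1807 genes at an unadjusted p below 0.05, the highest of the others being 1981, and 18 gave at least the real 17 lists, the highest of the others being 25.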
